A study of Arabidopsis thaliana with 12 samples.

How the data were processed

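The table analysed held 3439 probes in 12 samples of Arabidopsis thaliana, 6 labelled normal CO2 at 0 d and 6 labelled 6 d at 1% CO2, per the labels. Groups and sample numbers were taken from the labels, and every column was used. The deposited values are intensities on a linear scale, judged from the values themselves: none is negative, each sample has exact zeros, and each sample tops out at the same value just under 100. The array type, scanner, background correction and normalization the authors used are not given in the sources used here, so the meaning of a 0 and of the top value stays unknown. Several probes share the top value in most samples, and an intensity there may be a lower bound, while a 0 is given only as listed at 0. For arrays, the number of samples limits the precision.

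Sample medians of the deposited intensities lay between 0.648 and 1.58 times their mean, outside the 10% set beforehand, so the samples were quantile normalized (limma 3.58.1, R 4.3.3). Deposited zeros were kept at 0. Values under a common floor of 0.0398, the highest of the samples' 1st percentiles of positive normalized values, were raised to it, which floored 12.5% of probes per sample, and log2 was taken. Folds of dim probes are understated by the floor. The rule written before the data were examined gave each sample its own floor. Taken literally, tied zeros then gave a probe listed at 0 in all samples a fold, so the common floor replaced it after the data had been seen, and the literal form was run as an alternative. Linear intensities given as means are normalized intensities before the floor. Folds come from the difference of mean log2 values after the floor, so they can differ from the ratio of those linear means.

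A model with group as its only term was fitted per probe with lmFit and eBayes to 3349 probes, leaving out 90 that lay at the floor in all 12 samples, with Benjamini-Hochberg adjustment at 0.05. Replicates were to be averaged if sets of samples, the same in both groups, had every within-set residual correlation above 0.3 and above every between-set one. Pairs 1-2, 3-4 and 5-6 had within-pair residual correlations from 0.126 to 0.666 at high CO2 and from 0.217 to 0.882 at normal CO2. Between-pair values reached -0.0762 and 0.106. The rule was not met, because some within-pair values lay under 0.3, and the fit on 12 samples stayed the first one. The counts of calls had been seen when this was read. The fit on pair means, an alternative fixed beforehand, is given beside it. A random block for the pairs (statmod 1.5.0, consensus correlation 0.785) and fits without samples 5 and 6 were added after seeing the data.

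Probes were named through the platform annotation, dated 2016: 692 probes had 1 gene, 870 had several and 1877 had none given. Of the 692, 690 matched the RefSeq genes of TAIR10.1 by gene identifier, for 689 loci, and this assembly was used only for names. Probes with several genes or none stayed in the fit and unnamed. The named genes follow a rule fixed beforehand. It takes the 10 largest log2 rises and the 10 largest falls among single-gene probes that passed with all samples of the 2 groups separated, and from each gene list up to 3 measured members with the lowest p. A gene with several probes was represented by its brightest. The 22 gene lists (382 entries, 375 loci) were written from general knowledge around plastid functions, because the study the labels cite dealt with nuclear genes of chloroplast proteins. 23 of their loci had a tested single-gene probe, called measured here, 11 lists had no such member, and only the plastid ribosomal protein list had at least 5, so it alone was tested as a set with camera (preset correlation 0.01, and estimated) and fry. Median and total intensity per sample were compared by two-sided exact permutation tests.

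The procedure was tested on simulated data made from these 12 samples, with 200 of 3349 probes changed. The fit on 12 samples recovered 49% of 2-fold and 87% of 4-fold changes with 2 false calls. The simulated samples were drawn independently, without the likeness within pairs seen in the real samples. The 2 false calls therefore do not measure how many of the real calls over 12 samples are false. The fit on pair means recovered 0% of 2-fold and 48% of 4-fold changes with 5 false calls. A count of 0 over pair means therefore leaves 2-fold changes, and many 4-fold ones, open. Alternatives covered the scaling, the floor or offset, the filter on dim probes, the replicate number as a block, other pairs, the variance model, a fold threshold and each sample left out.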

Results

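Transcript levels were measured with 3439 array probes in 12 total RNA samples of wild-type Arabidopsis thaliana plants of the Columbia 0 ecotype. 6 samples came from plants grown at normal CO2 and labelled 0 d, and 6 came from plants kept for 6 d at 1% (v/v) CO2, a level far above that of air. The question the labels pose is which transcripts differ between plants at high CO2 and plants at normal CO2. The labels give neither the organ sampled nor the age of the plants at harvest, so the CO2 level and 6 d of growth may differ together. Deposited intensities lay on a scale from 0 to 100, and 133 to 398 probes per sample were listed at 0. Nothing states whether the 6 samples of a group came from separate plants, so p-values over the 12 samples measure the spread between these samples, which may be technical. Samples 1 and 2, 3 and 4, and 5 and 6 of each group resembled repeats: each of the 12 samples correlated best with its partner (Pearson r across probes from 0.919 to 0.981). Results are therefore given over 12 samples and over the means of these pairs, 3 per group. For single genes the SDs, SEs and p-values are over the 12 samples unless stated otherwise, and so may count repeats as replicates.

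Among the members of gene lists fixed before the data were examined, LHB1B2, also known as LHCB1.5 and encoding a chlorophyll a/b-binding protein of the photosystem II antenna, was 2.06-fold higher at high CO2. Its normalized intensity was 4.94 ± 0.30 at high CO2 and 2.40 ± 0.16 at normal CO2 (SD, n = 6 each). SBPASE, the sedoheptulose-bisphosphatase of the Calvin-Benson cycle, was 0.582 times its normal-CO2 level, with 0.483 ± 0.0875 against 0.835 ± 0.195 (SD, n = 6 each). NTRC, a plastid thioredoxin reductase that uses NADPH, was at 0.656 times and SRX, a sulfiredoxin that repairs peroxiredoxins, at 0.43 times the normal-CO2 level. All 4 passed the limma test over 12 samples after Benjamini-Hochberg adjustment, but each lost its call with another scaling. LHB1B2 did not pass after median scaling (log2 change 0.352), and SBPASE, NTRC and SRX did not pass with values as deposited (log2 changes -0.526, -0.099 and -0.716). None of the 3349 tested probes passed over pair means, where the smallest adjusted p was 0.407 and 408 probes had an unadjusted p under 0.05.

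Over the 12 samples, 418 probes passed (12.5% of those tested), of which 185 rose and 233 fell at high CO2. The split depended on the scaling: 326 rose and 65 fell with the values as deposited, where the median probe shifted by 0.449 on the log2 scale, and 85 rose and 246 fell after median scaling. With pairs as a random block in limma, 0 probes passed, 511 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0993. Among the 418, 77 probes carried a single gene name, of which 40 rose and 37 fell. The size of the log2 change among the 418 had a median of 1.08 and ran from -3.26 to 2.61, and 239 changed by at least 2-fold.

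The largest rise among named genes was that of AT3G56810, at 5.78 ± 0.803 at high CO2 against 1.17 ± 0.722 at normal CO2 (SD, n = 6 each), a 6.08-fold difference (log2 change 2.61, SE 0.43, limma adjusted p = 0.00696). Its pair means were 5.30, 6.37 and 5.67 at high CO2 and 1.19, 1.97 and 0.359 at normal CO2. The limma fit over pair means gave an adjusted p = 0.407 (unadjusted p = 0.00327). AT1G27610 rose by 2.28 on the log2 scale (adjusted p = 0.0271), but normal-CO2 samples 5 and 6 lay at the floor set before taking log2. With each sample's own floor its change was 3.55 and the call ended (adjusted p = 0.121), as it did after median scaling (adjusted p = 0.0669). AT5G02050 had 1 normal-CO2 sample at the floor and also lost its call with each sample's own floor (adjusted p = 0.0569). PRA1.B6, of the prenylated Rab acceptor family of membrane traffic proteins, rose by 2.23 (adjusted p = 0.0068), from 0.233 ± 0.112 to 0.969 ± 0.186 (SD, n = 6 each). The log2 rises of AT4G35660, AT5G63390, AT5G39980 and AT5G64150 were 2.08, 1.98, 1.68 and 1.60. Those of AT5G46560, AT5G02050 and AT2G28540 were 1.47, 1.39 and 1.36. Without samples 5 and 6 of both groups all 10 rises were smaller. Those of AT3G56810, AT5G63390, AT5G46560 and AT5G02050 were then 1.92, 1.18, 0.995 and 0.732. In each of these 10 genes all 6 high-CO2 samples lay above all 6 normal-CO2 samples, a condition of the rule by which they were chosen.

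The largest fall among named genes was that of AT2G26110, from 0.827 ± 0.137 at normal CO2 to 0.241 ± 0.149 at high CO2 (SD, n = 6 each), a log2 change of -2.07 (SE 0.486, limma adjusted p = 0.0196). Over pair means its limma adjusted p was 0.407 (unadjusted p = 0.0129). High-CO2 sample 5 was listed at 0 for this gene and lay at the floor. The call of AT2G26110 ended with each sample's own floor (log2 change -2.97, adjusted p = 0.16) and with values as deposited (log2 change -2.001, adjusted p = 0.107). Without samples 5 and 6 of both groups its log2 change was -1.24. AT1G62780, AT4G37230 and AT1G70180 changed by -1.92, -1.65 and -1.59 on the log2 scale. Some of their high-CO2 values lay at the floor too, in 1, 2 and 3 samples respectively, so these folds depend on the floor, and the call of AT1G70180 ended with each sample's own floor (adjusted p = 0.0586). CBL, the cystathionine beta-lyase of methionine synthesis, fell from 0.676 ± 0.176 to 0.276 ± 0.113 (SD, n = 6 each; log2 change -1.36, adjusted p = 0.0135). SECE1, a subunit of the Sec translocase of the thylakoid membrane, fell from 0.698 ± 0.156 to 0.292 ± 0.0812 (SD, n = 6 each; log2 change -1.28, adjusted p = 0.0111). LPA19, a factor in photosystem II assembly, fell from 0.725 ± 0.237 to 0.336 ± 0.113 (SD, n = 6 each; log2 change -1.15, adjusted p = 0.0295). The log2 changes of AT3G57630, AT1G03810 and AT1G51350 were -1.34, -1.13 and -1.13.

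**Figure D1:**
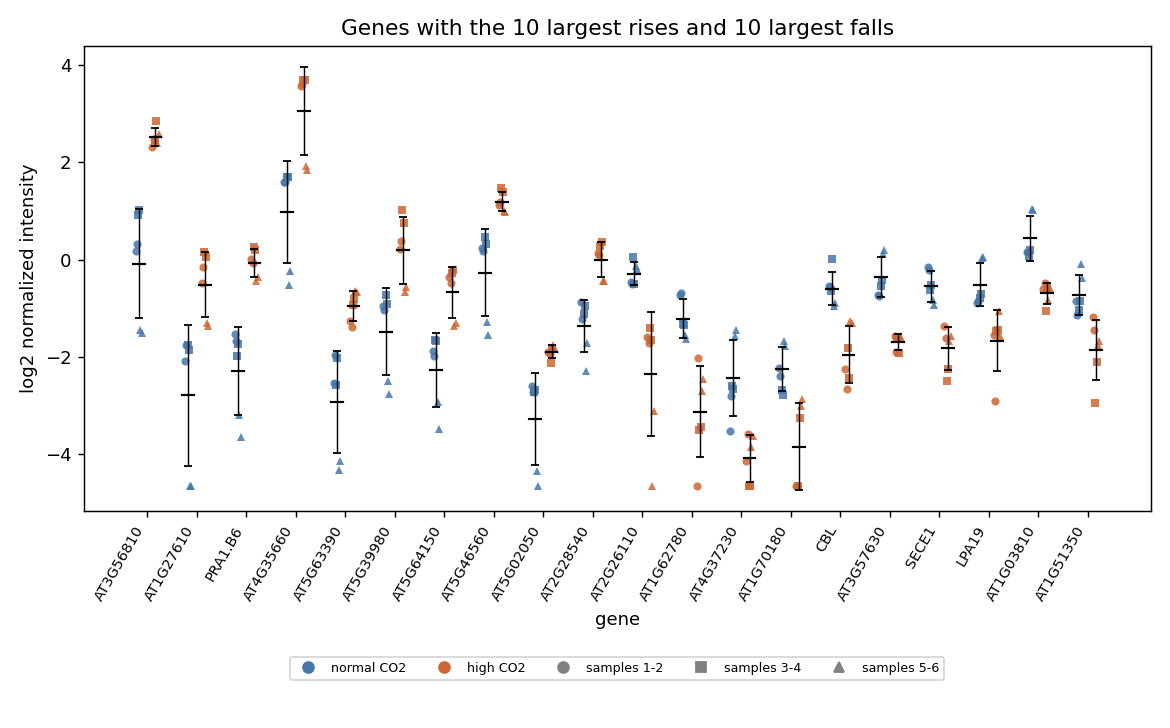
Log2 normalized intensity (vertical axis) of the 10 named genes with the largest rises and the 10 with the largest falls (horizontal axis); points are samples, with shapes for samples 1-2, 3-4 and 5-6, black lines are means and bars are SD over n = 6. The 2 groups do not overlap in any of the 20 genes, which was a condition for choosing them. In all 10 rises the normal-CO2 samples 5 and 6 sit below the other 4 normal-CO2 samples. Among the falls they sit above those 4 in AT4G37230, AT1G70180, AT3G57630, LPA19, AT1G03810 and AT1G51350, and below them in AT1G62780, CBL and SECE1. Among the rises, high-CO2 samples 5 and 6 also sit below the other 4 high-CO2 samples in most genes. These are AT1G27610, PRA1.B6, AT4G35660, AT5G39980, AT5G64150, AT5G46560 and AT2G28540, but not AT3G56810, AT5G63390 and AT5G02050.

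Only 9 of the 24 named genes that passed over 12 samples also passed with both other scalings. These were AT3G56810, PRA1.B6, AT5G63390, AT5G64150, AT5G02050 and AT2G28540, which rose, and AT1G62780, CBL and SECE1, which fell. The call of LHB1B2 ended after median scaling (log2 change 0.352, adjusted p = 0.424), as did those of AT4G35660 and AT5G46560, whose changes were then 1.23 and 0.889, and of AT5G39980. With values as deposited, the change of NTRC was -0.099 (adjusted p = 0.824), that of AT4G37230 -0.938 (adjusted p = 0.247), that of AT1G51350 -0.705 (adjusted p = 0.198), that of SBPASE -0.526 (adjusted p = 0.104) and that of LPA19 -0.766 (adjusted p = 0.168), and none of these 5 passed. AT3G57630 and AT1G03810 did not pass as deposited either (adjusted p = 0.0572 and 0.0535). The calls of SRX and AT1G70180 ended with both scalings. SRX had a change of -0.716 (adjusted p = 0.264) as deposited and of -1.304 (adjusted p = 0.071) after median scaling. Its call also ended with each sample's own floor (adjusted p = 0.118). AT1G70180 had a change of -1.372 (adjusted p = 0.136) as deposited and of -1.99 (adjusted p = 0.058) after median scaling.

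In the light-harvesting antenna list LHB1B2 was the 1 measured member, so adjustment over the list alone leaves its p unadjusted. It rose over all genes tested. Its pair means were 5.14, 4.99 and 4.68 at high CO2 and 2.50, 2.35 and 2.34 at normal CO2. Over these the limma adjusted p was 0.407 (unadjusted p = 0.00489). The LHCB1 genes are nearly identical in sequence, so the probe's signal cannot be assigned to LHB1B2 alone. Of the photosystem II subunits, 3 were measured and 0 passed: PSBW was at 32.7 ± 0.819 against 27.7 ± 9.26, PSBY at 1.83 ± 0.36 against 2.39 ± 0.967, and PSB27 at 2.92 ± 0.337 against 2.87 ± 1.23 (high against normal CO2, SD, n = 6 each). The signs of PSBW and PSB27 turned after median scaling, to -0.126 and -0.50 on the log2 scale. PSAN, the 1 measured photosystem I subunit, did not pass, at 5.23 ± 0.355 against 6.41 ± 1.34 (SD, n = 6 each). Without samples 5 and 6 of both groups, a fit chosen after seeing the data, 1270 of the 3349 tested probes passed. Over the remaining pair means 0 did. PSBY and PSAN were among the 1270, with log2 changes of -0.824 and -0.431 (limma adjusted p = 0.00816 and 0.0112). Over all 12 samples these changes were -0.293 and -0.266.

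Of the Calvin-Benson cycle list, 2 members were measured and 1, SBPASE, fell, also adjusted over the list alone. PRK, the phosphoribulokinase, was at 3.2 ± 0.709 at high CO2 and 4.92 ± 2.47 at normal CO2 (SD, n = 6 each; limma adjusted p = 0.43). In photorespiration the 1 measured member, LrgB, known as the plastid glycolate and glycerate transporter PLGG1, had a log2 difference of -0.175 (adjusted p = 0.776), which was 0.028 with values as deposited. PRK and LrgB were also among the 1270 of 3349 probes that passed without samples 5 and 6 of both groups. Their log2 changes were then -1.18 and -0.924 (limma adjusted p = 0.00233 and 0.00245) against -0.451 and -0.175 over all 12 samples. PRK, LrgB, PSBY and PSAN were also among the 482 probes that passed without normal-CO2 samples 5 and 6 alone. None of the 4 passed over pair means. Of the antioxidant and redox list, 3 members were measured. NTRC (log2 change -0.61, adjusted p = 0.023) and SRX (-1.22, adjusted p = 0.0428) fell over all genes tested. Adjusted over the list alone, 2 fell and 1 was higher, the latter being AT3G52960, a peroxiredoxin (log2 difference 0.555, adjusted p = 0.0967 over all genes), which also passed over all genes with values as deposited (0.788, adjusted p = 0.0324). NTRC pair means were 0.22, 0.219 and 0.219 at high CO2 against 0.363, 0.359 and 0.287 at normal CO2. The SRX samples of the 2 groups overlapped.

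Over the 12 samples, no measured member of the remaining lists passed over all genes or adjusted over the list alone. These were CHLM and AT1G74470 in chlorophyll synthesis (log2 differences -0.127 and 0.08) and APS4 in sulfate assimilation (-0.38). AT3G58610 and AT3G23940 in branched-chain amino acid synthesis differed by -0.181 and 0.053, and AT1G24360 and FATB in plastid fatty acid synthesis by -0.665 and 0.259. The AT1G24360 difference rested largely on normal-CO2 sample 3 and was -0.255 without it. FATB passed with values as deposited, at 0.817 (adjusted p = 0.0175). The signs of CHLM, APS4 and AT3G58610 turned with values as deposited, and those of AT1G74470 and AT3G23940 after median scaling. Without samples 5 and 6 of both groups, where 1270 of 3349 probes passed, AT1G74470 and AT3G23940 passed as lower. Their log2 differences were then -0.495 and -0.813 (limma adjusted p = 0.0391 and 0.00387). The ribosomal protein gene AT3G13120 then passed too, at -0.739 (adjusted p = 0.00941). None of them passed over pair means. Of the plastid ribosomal proteins, 5 were tested, 3 with a positive and 2 with a negative difference, and 0 passed. Examples were AT1G64510 (log2 difference -0.666, adjusted p = 0.107), AT3G54210 (0.121) and AT3G13120 (-0.201). The list had a median log2 difference of 0.054 and a mean of -0.091, which differ in sign, and no shift against the other probes was detected (camera p = 0.754, p = 0.808 with an estimated correlation). Over pair means the camera p was 0.706. The fry test of limma, which asks whether the genes of the list move on balance one way, gave an adjusted p = 0.693, and its mixed test, for change in either direction, an adjusted p = 0.871, equal to the unadjusted values because 1 list was tested. Of 11 lists no member had a probe of its own with a single gene name, though members may lie on probes with several gene names or none: photosynthetic electron carriers and ATP synthase, carbonic anhydrases, starch synthesis, starch breakdown and sugar export, isoprenoids and carotenoids, plastid protein import and chaperones, plastid proteases, jasmonate synthesis, sigma factors, senescence and starvation markers, and root-type plastid isoforms.

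**Figure D2:**
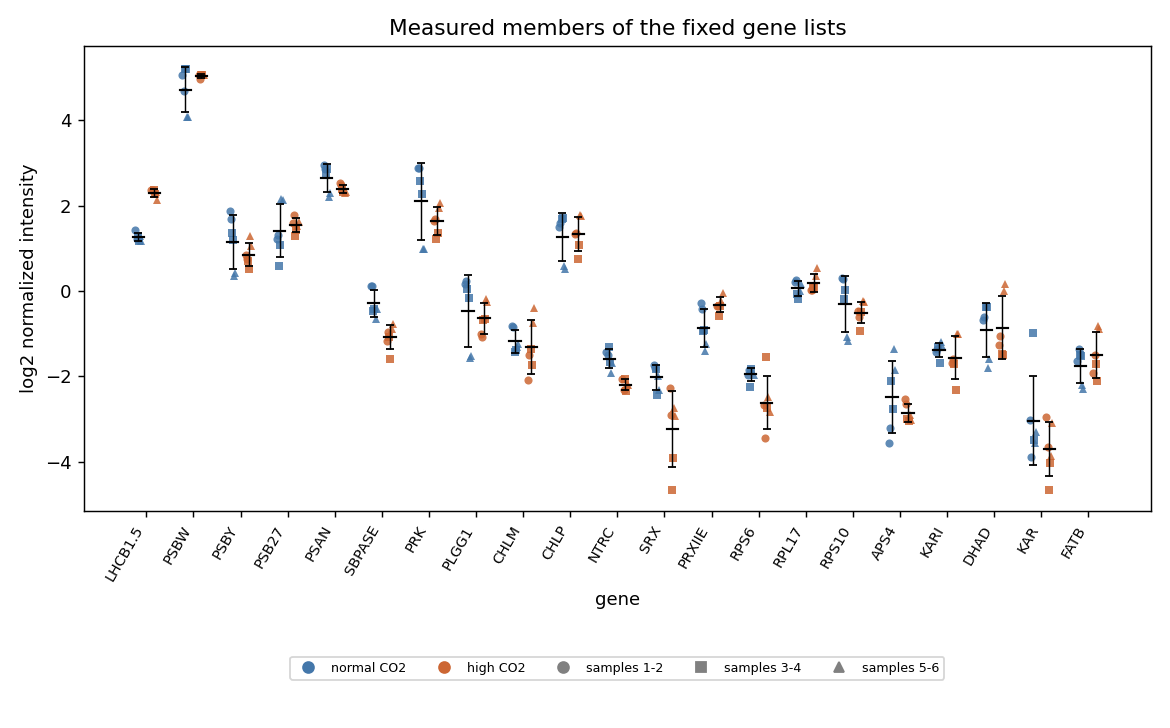
Log2 normalized intensity (vertical axis) of 21 measured members of the fixed gene lists (horizontal axis, by list symbol); points are samples, with shapes for samples 1-2, 3-4 and 5-6, black lines are means and bars are SD over n = 6. In LHCB1.5 (LHB1B2) all high-CO2 samples lie above all normal-CO2 samples, a call that ended after median scaling, while in PRK and PSBW the groups overlap and the normal-CO2 samples 5 and 6 lie below the other normal-CO2 samples.

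Samples 5 and 6 of both groups stood apart from the other 4 of their label. The samples labelled high CO2 5 and 6 correlated more closely with normal-CO2 samples 1 to 4 (r across probes from 0.901 to 0.917) than with high-CO2 samples 1 to 4 (0.837 to 0.866). The samples labelled normal CO2 5 and 6 correlated with normal-CO2 samples 1 to 4 at 0.796 to 0.803 and with high-CO2 samples 1 to 4 at 0.726 to 0.781. These are correlations across probes, which are not independent replicates. Without samples 5 and 6 of both groups, an alternative chosen after seeing the data, 608 probes were higher and 662 lower at high CO2 over 8 samples. Over the remaining 2 pair means per group 0 passed, with 1059 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0717. Leaving out single samples moved the number of probes passing between 230, without high-CO2 sample 3, and 580, without high-CO2 sample 5. It was 266, 242 and 240 without high-CO2 samples 1, 2 and 4, and 270 without normal-CO2 sample 5.

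**Figure D3:**
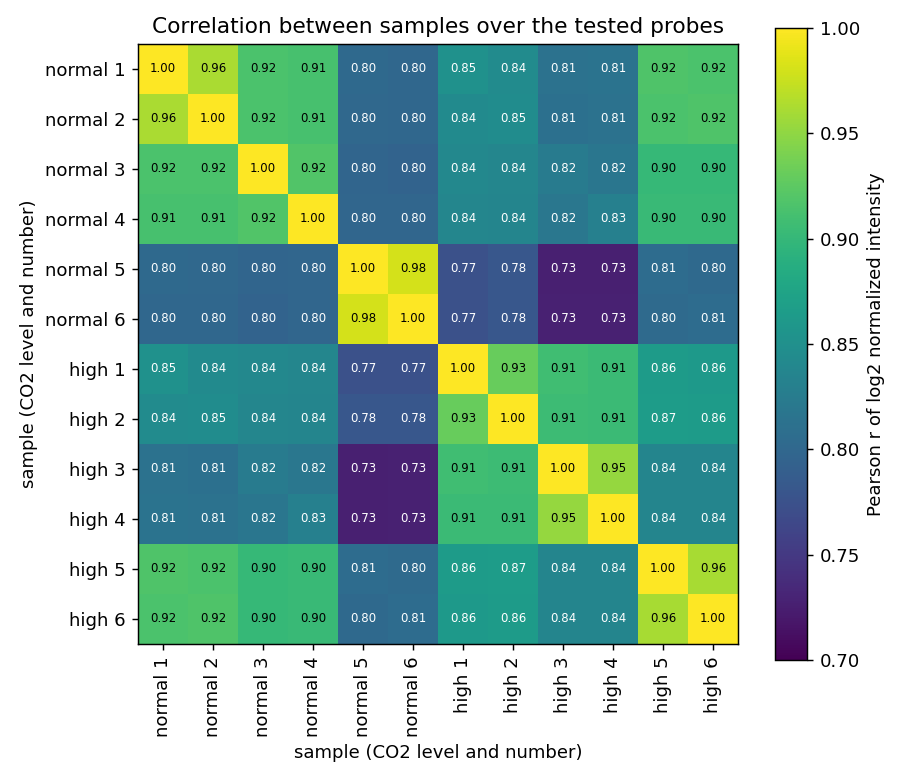
Pearson correlation of log2 normalized intensity across tested probes between each pair of the 12 samples (both axes: CO2 level and sample number; colour from 0.7 to 1, with the value in each cell). High-CO2 samples 5 and 6 reach 0.901 to 0.917 with normal-CO2 samples 1 to 4, and normal-CO2 samples 5 and 6 reach 0.803 at most with them.

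The median deposited intensity per sample was 0.301 ± 0.100 at high CO2 and 0.194 ± 0.0475 at normal CO2 (SD, n = 6 each), a difference of 0.107 (two-sided exact permutation p = 0.0303). Over pair means the same difference had an exact two-sided p = 0.2, where 3 against 3 can give no p below 0.1. High-CO2 samples 1 to 4 had medians from 0.34 to 0.39, and high-CO2 samples 5 and 6 had 0.174 and 0.175. Normal-CO2 samples 1 to 4 had medians from 0.16 to 0.166, and normal-CO2 samples 5 and 6 had 0.256 and 0.255. The total deposited intensity was 3223 ± 172 at high CO2 and 3105 ± 191 at normal CO2 (SD, n = 6 each; two-sided exact permutation p = 0.29, and 0.6 over pair means).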

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

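Of 88 groups of 6 samples tested for a value far from the others, 4 were flagged. In these the gap of the lowest or highest sample to the nearest other, as a share of the group's whole range, exceeded 0.625. Chance gives about 1 in 20 such groups if the 6 values are independent and normally distributed. The likeness within pairs and tied values go against this, so that rate may not hold here. LPA19 at high CO2 had sample 2 at -2.902 on the log2 scale, with the other 5 between -1.584 and -1.057 (share 0.714). PSBW at high CO2 had sample 2 at 4.957 while the other 5 shared one value after quantile normalization, 5.047 (share 1). AT1G64510 at normal CO2 had sample 3 at -2.248, with the others between -1.974 and -1.819 (share 0.639). AT1G24360 at normal CO2 had sample 3 at -0.9824, with the others between -3.876 and -3.019 (share 0.704).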

How the results depend on the processing

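Of the alternatives below, each sample's own floor, the random block for pairs and the fits without samples 5 and 6 were chosen after seeing the data. The 24 named genes that passed kept their sign with the other scalings, floors and the offset; most other settings leave the sign fixed by construction. The cause of the changes below was not tested. The floor limits the folds of probes with samples at it, and 12.5% of probes per sample lay there. The 418 probes (185 higher, 233 lower) became 326 higher and 65 lower with values as deposited, 85 and 246 after median scaling, and 118 and 159 with each sample's own floor. Both averaging pairs 1-2, 3-4 and 5-6 and the random block for pairs gave 0 higher and 0 lower in limma (408 and 511 at unadjusted p under 0.05). Floor at the 5th percentile, offset, removal of dim probes, variance trend, an unmoderated model, averaged pairs 1-4, 2-5 and 3-6 and a 1.5-fold threshold gave counts within 1.5 times (335 to 465 in all, with 181 higher and 223 lower at 1.5-fold). Averaging 1-4, 2-5 and 3-6 puts the members of each likely repeat pair into different averages. Its count therefore does not guard against repeats. Without high-CO2 samples 5 and 6 there were 431 higher and 469 lower, without those labelled normal CO2 193 and 289, without both 608 and 662, and over pair means without pair 5-6 0 and 0 (1059 at unadjusted p under 0.05 in limma). Leaving out 1 sample gave 90 to 264 higher, 140 to 316 lower.

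Over all tested probes the sample numbers showed little pairing across groups. Same-numbered residual correlations ran from -0.0784 to 0.158, and 4 of 12 samples correlated best with their own number. A fit with the replicate number as a block called 460 probes, 222 higher and 238 lower, against 418 without it. Single genes differed in this. AT4G35660 pair means followed the numbers, at 12, 12.9 and 3.69 (high CO2) and 3.01, 3.25 and 0.775 (normal CO2). Those of PRK did not, at 3.17, 2.43 and 3.99 against 7.38, 5.41 and 1.98. A factor shared by same-numbered samples is therefore not excluded.

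Of the 24 called genes, 10 lost their call with values as deposited, 7 after median scaling and 5 with each sample's own floor. With averaged pairs 1-2, 3-4 and 5-6 and with the random block for pairs 24 lost it. Without normal-CO2 samples 5 and 6, 7 lost it. The unmoderated model lost 3 calls (AT1G27610, AT5G02050 and SRX). Averaged pairs 1-4, 2-5 and 3-6 lost 1 (NTRC), as did leaving out samples 5 and 6 of both groups (AT1G51350). Leaving out 1 sample keeps its pair partner in the fit, so it cannot show dependence on a whole pair. In this test 16 genes kept their call each time. The other 8 lost it without at least 1 sample: SBPASE (high-CO2 4, adjusted p = 0.0514), AT1G51350 (high-CO2 4, normal-CO2 5 or 6, up to 0.0643), AT4G35660 and AT1G27610 (any of high-CO2 1 to 4, up to 0.057 and 0.0643), AT5G02050 and AT5G39980 (these or normal-CO2 5, up to 0.0625 and 0.062), LPA19 (high-CO2 1, 3 or 4, normal-CO2 5 or 6, up to 0.0608) and SRX (9 of the 12 samples, up to 0.0956). AT1G64510 passed without high-CO2 sample 3 (adjusted p = 0.0291).

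Values that turned sign were, with values as deposited, LrgB 0.028, CHLM 0.323, APS4 0.327, AT3G58610 0.319 and the ribosomal list mean 0.288; after median scaling PSBW -0.126, PSB27 -0.50, AT1G74470 -0.529, AT3G54210 -0.331 and AT3G23940 -0.161; with each sample's own floor the ribosomal list mean 0.056. Without high-CO2 samples 5 and 6 they were AT1G74470 -0.134, AT3G54210 -0.009, AT3G23940 -0.415 and FATB -0.059, and without normal-CO2 samples 5 and 6 PSBW -0.001, AT1G74470 -0.282, APS4 0.057 and AT3G23940 -0.344. Without both, over samples and pair means alike, they were PSBW -0.008, AT1G74470 -0.495, APS4 0.107, AT3G23940 -0.813 and FATB -0.31. Over samples, 1270 of the 3349 tested probes then passed. AT1G74470 and AT3G23940 were among them (limma adjusted p = 0.0391 and 0.00387), as were PSBY, PSAN, PRK, LrgB and AT3G13120, all lower. These last 5 also passed without normal-CO2 samples 5 and 6 alone. Leaving out 1 sample gave ranges of -0.159 to 0.008 for the ribosomal list mean, -0.309 to 0.03 for CHLM, -0.036 to 0.274 for PSB27, -0.072 to 0.198 for AT1G74470 and -0.151 to 0.184 for AT3G23940. The ribosomal list did not pass in any setting in which it was tested, which leaves out the unmoderated model and the random block for pairs. The median intensity difference of 0.107 did not pass over pair means and ran from 0.0895 to 0.133 with 1 sample left out, not passing without any of high-CO2 samples 1 to 4 (p up to 0.0866).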

Other observations

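Over pair means, LHB1B2 had a log2 SD of 0.0706 at high CO2 and 0.0529 at normal CO2, against a log2 change of 1.04. For NTRC these SDs were 0.00532 and 0.191 against a change of -0.61, and for AT3G57630 0.0897 and 0.46 against -1.34. Within pairs NTRC spread more, with high-CO2 samples 1 and 2 at -2.05 and -2.33. The LHB1B2 change was 0.352 after median scaling, and those of NTRC and AT3G57630 were -0.099 and -0.989 as deposited. None of these genes passed over pair means. In 607 of the 3349 tested probes (18.1%) all 3 high-CO2 pair means lay on the same side of all 3 normal-CO2 pair means, which chance gives in 10% of independent probes. Among the 9 other splits of the 6 pairs, the exchange of pair 5-6 between the groups separated 751 probes and the other 8 separated 114 to 398, so the excess is not particular to the labels.

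The test of exchanged labels, the test of normal-CO2 RNA in samples 5 and 6, which replaced one that only restated the pattern, and the comparison with normal-CO2 samples 5 and 6 were chosen after the results were seen. The samples labelled high CO2 5 and 6 lay nearer the normal-CO2 samples: on an axis built from samples 1 to 4, running from about -0.5 at normal CO2 to 0.5 at high CO2, they scored -0.256, and from -0.339 to -0.235 over the scalings and floors. Raised dim probes on high-CO2 samples 1 to 4 are argued against by the score over the brightest 25% of probes, -0.183, still on the normal-CO2 side. An exchange of labels cannot be told apart, because the samples labelled normal CO2 5 and 6 scored -0.206, from -0.228 to 0.073 over the same settings. Over the brightest 25% of probes these normal-CO2 samples scored -0.239. A weaker response to high CO2 also cannot be told apart. On axes built without the set scored, high-CO2 samples 5 and 6 averaged -0.212. They lay above the held-out normal-CO2 pairs (-0.267 and -0.379), as predicted beforehand. So did normal-CO2 samples 5 and 6 (-0.061 and -0.274), a comparator added afterwards without which the test favoured this explanation. Normal-CO2 RNA in high-CO2 samples 5 and 6 cannot be told apart either. Of probes called from high-CO2 samples 1 to 4 and 1 normal-CO2 pair, they lay on the high-CO2 side in 36.1% and 27.5%. This was more than for the held-out normal-CO2 pair (21.1% and 15.3%), but normal-CO2 samples 5 and 6 did so in 44.7% and 39%.

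Probes passed over 12 samples and not over pair means. Repeats counted as replicates may account for this: of the 9 other splits that keep pairs whole, 1 gave 642 calls, more than the 418 of the labels. That split exchanges pair 5-6 between the groups and points to a structure of the samples; over pair means it gave 3 calls and 545 probes at an unadjusted p under 0.05 in limma, against 0 and 408 for the labels. The other 8 gave 0 to 58 calls over 12 samples, so the test rests on the doubted samples.

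Of 100 splits of the 12 samples drawn from 462, the labels included, 1 gave as many as 418 probes, the labels themselves, and the highest other of those drawn gave 58. This excludes chance only if the 12 samples are independent, which the likeness within pairs argues against, and the 100 drawn did not include the exchange of pair 5-6. Of the 10 splits that keep pairs whole, 2 gave as many, the labels with 418 and the exchange of pair 5-6 with 642; 10 splits are too few for a share under 0.05.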
